A study of Homo sapiens with 12 samples.

How the data were processed

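Newly made RNA was measured by SLAM-seq in 12 libraries of 22Rv1 cells, a human prostate cancer line, gene-edited to express SF3B1 with the substitution C1111S. Per the labels' protocols, cells received DMSO (0.1% v/v), WX-02-23 (20 µM), WX-02-43 (20 µM) or PladB (10 nM) and then 4-thiouridine (100 µM, 1 h). The compounds were applied for 3 h. RNA was alkylated with iodoacetamide, which makes incorporated 4-thiouridine read as C where the genome has T, and 3′ end libraries were made with a QuantSeq kit, per the labels' protocols. A read with such a change is called a T>C read below, and is taken as a read of RNA made during the labelling. Each of the 4 groups had 3 libraries, numbered by replicate. The labels do not say whether replicates were separate cultures, so the p-values measure the spread between these samples. No library without 4-thiouridine was analysed here, so T>C reads from sequencing errors or variants could not be subtracted.

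Per the file headers, reads were mapped, filtered and counted with slamdunk 0.4.3 over 3′ UTR intervals of curated RefSeq transcripts and spike-in sequences; the genome build was hg19, per the submitters' processing notes. The deposited files give per interval raw read counts, T>C read counts, multimapping read counts, and counts of covered T positions and of T>C conversions. The authors also deposited CPM per interval, and the ratio of each count to its CPM gave 1 library total per file. The deposited conversion rate is the fraction of covered T positions that were converted. Only the counts entered the tests, and the CPM column gave the library totals.

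The files held 29255 intervals, of which 709 were spike-ins, 23086 belonged to coding transcripts and 5460 to noncoding transcripts. The noncoding intervals were all on the minus strand and had a median length of 8233 bases, against 938.5 for coding intervals, and they held 27.1% of T>C reads summed over intervals. They were therefore left out of the main tests and are described in the closing part on data outside the comparisons. Of 3867 noncoding genes with a strand in GENCODE release 29, only 26 were on its plus strand. Noncoding genes of the plus strand were thus largely absent from the files. Intervals of 1 gene were joined so that a read in overlapping intervals of that gene counted once, since plain sums counted over 1.1 times as many reads in 1846 coding genes. The design written before the files were seen had said that the intervals of a gene would be summed. The joined coding intervals were thus chosen after the files were seen, and the plain sum over every interval was run as an alternative. Of 45 interval names turned into dates, 44 were restored from transcript accessions, and 19 pseudoautosomal intervals on chromosome Y were left out. This gave 18651 coding genes. Gene positions are the outer bounds of these intervals in hg19. Exon numbers came from GENCODE release 29 for 97.2% of genes by name, and no coordinates of that release are printed.

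Library totals behind the CPM column ran from 24670716 to 42190854 reads. Reads on coding genes ran from 12331501 to 21414162 per library, and T>C reads on coding genes from 826620 to 2094217. Between replicates, the variance of gene counts with means from 20 to 500 was a median of 21.9 times the mean for T>C reads and 21.6 times for all reads, far more than counting error alone gives. The reads carry no molecular identifiers, so floors that rest on counts cover counting error only. The intervals given for log2 changes come from the edgeR fit described below, which includes the spread between replicates. Where every library of a group had 0 T>C reads, the fold is a lower bound against a floor of 3 counts per library.

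Genes were tested with edgeR 4.0.16 in R 4.3.3, using a quasi-likelihood fit to all 12 libraries with the group as the only term, TMM scaling, filterByExpr and Benjamini-Hochberg adjustment; adjusted p under 0.05 is a call. T>C reads were scaled to T>C reads, so that a change is relative to the typical gene of the newly made RNA. All reads were tested in the same way. The 4 comparisons were each compound with DMSO, and WX-02-23 with WX-02-43, which had the same dose and time. Values per gene are CPM of T>C reads, or of all reads where said, on the fitted scale, as mean ± SD with n = 3. Log2 changes are given with their standard error (SE), and intervals are 95%. The share of reads with T>C was compared by exact two-sided permutation tests. With 3 libraries against 3 the smallest p such a test can give is 0.1, and 10% of unchanged genes have groups that do not overlap.

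Gene lists written before the data were examined were tested with camera (limma 3.58.1) at its preset correlation of 0.01, for lists with at least 5 tested members. The 20 lists included prostate luminal lineage factors, immediate early genes, MYC and ribosome biogenesis genes, p53 targets, SF3b and U2 factors, SR and hnRNP splicing regulators, NRF2 and electrophile response genes, heat shock genes, integrated stress and unfolded protein response genes, apoptosis regulators, cell cycle genes, cholesterol synthesis genes, intronless genes, short-lived zinc finger and transcription regulators, and markers of neuroendocrine, basal, stromal and immune cells, and mitochondrially encoded genes. The comparisons, tests, lists and named-gene rule were also chosen before the data were examined. That rule named, per comparison on T>C reads, the 8 genes with the largest fitted rise and the 8 with the largest fall among called genes with a mean of at least 20 T>C reads in the higher group and groups that did not overlap, leaving out names that only number a locus or an open reading frame. It added FOXA1 and SF3B1 throughout, up to 4 members of each list by smallest unadjusted p, and for all reads the 5 genes with the largest rise and the 5 with the largest fall. Genes outside it are named as such. Some genes and 1 list that these rules cover are not reported here, though counts over all genes and lists include them.

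The tests were first tested on simulated data drawn from the means, depths and spread of the real libraries, with 200 genes changed between WX-02-23 and DMSO. In T>C reads, 3 of 100 genes changed 2-fold and 14 of 100 changed 4-fold were called, rising to 33.3% and 100% of those with a mean over 500 reads, with 0 false calls among 17. In all reads the test recovered 43 and 76 of 100, with 8 false calls among 132. A planted list of 30 genes raised 1.5-fold gave an unadjusted camera p of 0.0396 in T>C reads. In the simulated data most T>C changes of 2-fold in genes with fewer reads were thus missed. Unchanged groups simulated with the same spread varied more than the real stereoprobe changes, so the recovered shares may be too low. For the overlap of comparisons, 20 further sets of 12 libraries were drawn with every group, DMSO included, at the mean of the real DMSO libraries.

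Alternatives were median-ratio size factors, scaling of T>C reads by all reads, DESeq2 1.42.0, no filter on low counts, a filter on a mean of 20 T>C reads, a fit of only the 6 libraries compared, a term for the replicate number, each interval tested by itself, leaving out genes with over 10% multimapping reads, and leaving out each library in turn. For the lists they were camera with an estimated correlation and fry. The plain sum over every interval, the unit named in the design, became an alternative when the main unit was changed after the files were seen. Chosen after seeing the data were leaving out genes with under 1.2 conversions per T>C read and dividing counts by the variance ratio above. Leaving out PladB replicate 2 throughout was also chosen then.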

Results

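The libraries measured RNA newly made in 22Rv1 prostate cancer cells with C1111S-SF3B1 after 3 h of compound. SF3B1 is a core subunit of the SF3b complex, which binds the branch site in splicing, and the substitution replaces a cysteine with a serine. The series design sets out to profile transcriptome changes in these cells after stereoprobes or PladB, and its title concerns covalent small molecules and FOXA1, a pioneer transcription factor of luminal prostate cells. The DMSO, WX-02-23, WX-02-43 and PladB groups had 3 libraries each. WX-02-23 and WX-02-43 are code-named compounds that the labels call stereoprobes, and PladB is pladienolide B, an inhibitor of SF3b. Mean reads on coding genes were 16092000 in DMSO, 16634000 in WX-02-23, 15733000 in WX-02-43 and 17368000 in PladB. Mean T>C reads on coding genes were 1522300, 1609400, 1431300 and 948450 in the same order. Genes with at least 1 read ran from 11883 (PladB replicate 2) to 13177 per library, and genes with a T>C read from 7362 (also PladB replicate 2) to 10937.

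PladB lowered the share of reads with T>C, and neither stereoprobe shifted it beyond the spread between replicates. That share depends on how much RNA was newly made and on how heavily it was labelled. The share of coding-gene reads with T>C was 9.45% ± 0.43 (SD, n = 3) in DMSO and 5.44% ± 0.191 in PladB, a ratio of 0.576. All 3 PladB libraries lay below all 3 DMSO libraries, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows (0.267 after adjustment over 4 comparisons). WX-02-23 libraries stood at 9.64% ± 0.217, a difference of 0.195 percentage points from DMSO (exact permutation p = 0.7), which became -0.0379 without DMSO replicate 2. WX-02-43 libraries stood at 9.1% ± 0.277, a difference of -0.346 points (exact permutation p = 0.2), and the stereoprobes differed from each other by 0.541 points (exact permutation p = 0.2). The percent of covered T positions that were converted put the groups in another order, at 0.706% ± 0.0244 in DMSO, 0.811% ± 0.0156 in WX-02-23, 0.913% ± 0.0364 in WX-02-43 and 0.318% ± 0.00899 in PladB. On that measure WX-02-43 lay above DMSO and above WX-02-23, the reverse of the share of reads. Each of the 4 comparisons on it had groups that did not overlap, with an exact permutation p of 0.1.

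**Figure D1:**
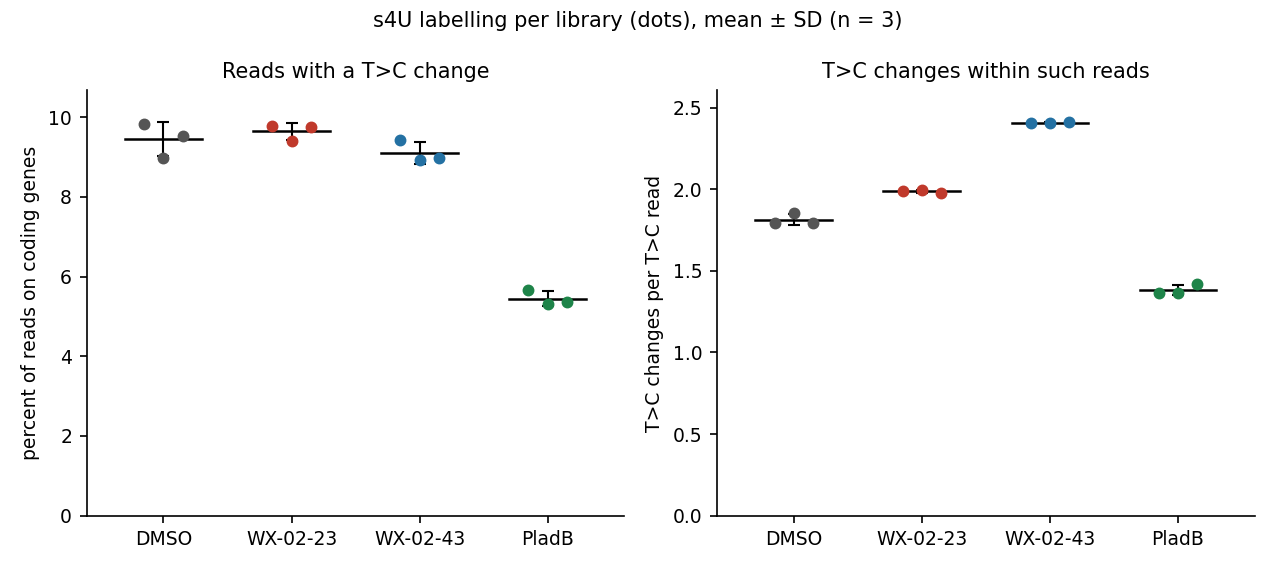
Share of coding-gene reads with T>C (percent, left) and T>C changes per T>C read (right) in DMSO, WX-02-23, WX-02-43 and PladB, with dots for libraries and bars for the mean ± SD of 3. PladB lies lowest in both panels (5.44% and 1.38), while WX-02-43 lies near DMSO on the left and highest on the right (2.41 against 1.81).

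The comparison of WX-02-23 with DMSO asks what the stereoprobe changes in cells whose SF3B1 has serine at this position. Newly made RNA of electrophile and oxidative stress genes rose after WX-02-23. These included TXNRD1 (thioredoxin reductase), OSGIN1 and HMOX1 (heme oxygenase), all known targets of NRF2. Transcripts of the stress genes GDF15, DDIT4 and SESN2 and of the metabolic regulator PDK4 also rose, while PMEPA1, a regulator of TGF-beta signalling, and the transcription factor genes TFAP2A, ZNF503 and TBX3 fell. FOXA1 and SF3B1 itself were not called. Of 10722 genes tested in T>C reads, 24 were called, 18 higher and 6 lower, and 14 of the higher and 1 of the lower changed at least 2-fold.

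TXNRD1 (chromosome 12, 104742200 to 104744085 in hg19, 3′ UTR) rose from 243 ± 44.4 CPM in DMSO to 1471 ± 101 in WX-02-23, a log2 change of 2.60 (SE 0.24, adjusted p = 1.23e-09, edgeR). OSGIN1 (chromosome 16, 83999613 to 83999937) had no T>C read in DMSO and 105 ± 20.6 CPM in WX-02-23, at least 55.4-fold higher (adjusted p = 0.000194). GDF15 (chromosome 19, 18499746 to 18499987) rose from 766 ± 30.5 to 2302 ± 159 CPM, a log2 change of 1.59 (SE 0.14, adjusted p = 6.36e-10). PDK4 (chromosome 7, 95212809 to 95214952) rose from 622 ± 148 to 1937 ± 236 CPM, with a log2 change of 1.64 (SE 0.18, adjusted p = 5.94e-08). DDIT4 (chromosome 10, 74034947 to 74035794) went from 153 ± 4.08 to 519 ± 82.1 CPM (log2 change 1.76, adjusted p = 0.000243). HMOX1 (chromosome 22, 35789592 to 35790207) went from 5.97 ± 9.81 to 183 ± 25.5 CPM (log2 change 4.89, SE 1.06, adjusted p = 0.0267). ARHGEF2 and IRS1 were the other rises among the 8 that the naming rule gives, by 2.40 (adjusted p = 0.0461) and 1.52 (adjusted p = 0.0101). Among falls, TFAP2A went from 2223 ± 306 to 1172 ± 205 CPM (log2 change -0.92, adjusted p = 0.000547) and PMEPA1 from 1152 ± 43.0 to 631 ± 43.6 CPM (log2 change -0.87, adjusted p = 0.00259). ZNF503 (log2 change -0.52, adjusted p = 0.00197), TBX3 (-0.54, adjusted p = 0.0183) and TUBB (-0.70, adjusted p = 0.0308) fell too. In TUBB 21.5% of reads were multimapping, so its value is uncertain. C9orf66 rose more than TXNRD1 (log2 change 2.62, adjusted p = 0.00785), but the naming rule leaves out names that only number an open reading frame. It, AMD1 and CD81 were named after their values were seen; ELF3, FTH1, HSPA1B, KLF6, SESN2 and SRXN1 were called as well.

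For the genes of the title and the cell line, the change after WX-02-23 was -0.21 in FOXA1 (95% interval -0.43 to 0.02, adjusted p = 1), from 2656 ± 300.1 to 2304 ± 252 CPM. SF3B1 changed by -0.27 with a wide interval (-1.37 to 0.83), at 73.7 ± 16.9 CPM in DMSO.

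Which calls held depended on single libraries. Leaving out each of the 6 libraries in turn kept 11 of the 24 genes called every time (DDIT4, FTH1, GDF15, OSGIN1, PDK4, PMEPA1, TFAP2A, TXNRD1 and ZNF503 among them), and no called gene changed sign. The count fell to 15 without DMSO replicate 2, 15 without WX-02-23 replicate 1 and 12 without WX-02-23 replicate 2. HMOX1 was no longer called without DMSO replicate 2 (adjusted p = 0.173) or 3 (0.0915), or without WX-02-23 replicate 1 (0.108), 2 (0.102) or 3 (0.118). ARHGEF2 and KLF6 lost the call whichever of the 6 libraries was left out, with adjusted p up to 0.292 and 0.294 without WX-02-23 replicate 2. IRS1 lost it without DMSO replicate 1 (0.0586) or 3 (0.0682), or without WX-02-23 replicate 2 (0.105) or 3 (0.0943). SESN2 lost it without DMSO replicate 1 (0.433) or 2 (0.0812), or without WX-02-23 replicate 1 (0.108), 2 (0.185) or 3 (0.0768). SRXN1 lost it without DMSO replicate 2 (0.124) or WX-02-23 replicate 1 (0.115), and HSPA1B without WX-02-23 replicate 2 (0.119). ELF3 lost it without DMSO replicate 2 (0.125) or 3 (0.127), or without WX-02-23 replicate 1 (0.159) or 2 (0.116). TBX3 lost it without DMSO replicate 1 (0.162) or 3 (0.0529), or without WX-02-23 replicate 2 (0.292) or 3 (0.0936). TUBB lost it without DMSO replicate 2 (0.945) or any WX-02-23 replicate (0.115, 0.109 and 0.188). AMD1 lost it whichever library was left out (adjusted p up to 0.310), C9orf66 without DMSO replicate 1 (0.0804) or 3 (0.0584) or WX-02-23 replicate 1 (0.0960) or 2 (0.0943), and CD81 without DMSO replicate 2 (0.169) or 3 (0.142) or WX-02-23 replicate 1 (0.0715) or 2 (0.632). At an unadjusted p under 0.05 there were 486 genes, and 1284 genes (11.98%) had groups that did not overlap, against the 10% that chance gives.

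By list, 6 of the 17 lists tested in T>C reads moved after WX-02-23, 5 up and 1 down, and 4 of them hold with an estimated correlation. NRF2 and electrophile response genes moved most, with 5 of 25 tested members called higher, 0 lower and 20 not called (10 higher when adjusted over the list alone). Their median log2 change was 0.73 (camera adjusted p = 1.08e-19, and adjusted p = 0.00354 with an estimated correlation). The 5 were TXNRD1, OSGIN1, HMOX1, SRXN1 (log2 change 1.41, adjusted p = 0.00785) and FTH1 (1.17, adjusted p = 0.000793). In FTH1, the ferritin heavy chain gene, 79.0% of reads were multimapping, so its value is uncertain. Heat shock genes rose by a median of 0.57 over 27 tested members (camera adjusted p = 7.24e-06, and adjusted p = 0.0283 with an estimated correlation). Of these, 2 were called higher, HSPA1B (log2 change 1.03, adjusted p = 0.00657) among them, 0 were lower and 25 were not called, with 5 higher when adjusted over the list alone. Integrated stress and unfolded protein response genes rose by a median of 0.21 over 32 members (camera adjusted p = 0.000478, and adjusted p = 0.0228 with an estimated correlation). DDIT4 and SESN2 (log2 change 1.06, adjusted p = 0.0324) were called higher, 0 lower and 30 not called, with 4 higher when adjusted over the list alone. CHAC1 (0.97, adjusted p = 0.483) and TRIB3 (0.82, adjusted p = 0.328) of that list were not called.

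Intronless genes rose by a median of 0.22 over 37 members (camera adjusted p = 0.00242, and adjusted p = 0.0340 with an estimated correlation), with HSPA1B called higher, 0 lower and 36 not called, and 6 higher when adjusted over the list alone. Immediate early genes rose by a median of 0.22 over 35 members (camera adjusted p = 0.00346), but not with the other correlation (adjusted p = 0.156 with an estimated correlation). KLF6 was their only called member (log2 change 0.74, adjusted p = 0.0436), with 4 higher when adjusted over the list alone, and JUN (0.51, adjusted p = 0.113) and EGR1 (0.64, adjusted p = 0.148) were not called. Cell cycle genes fell, with a median of -0.46 over 38 members (camera adjusted p = 0.000339, but adjusted p = 0.0534 with an estimated correlation), with 0 of 38 called and 2 lower when adjusted over the list alone, CCND1 (-0.36, adjusted p = 0.0604) and MCM7 (-1.01, adjusted p = 0.354) among its examples. Prostate luminal lineage factors (camera adjusted p = 0.091) had ELF3 higher (log2 change 1.01, adjusted p = 0.0201), 2 lower, TFAP2A among them, and 24 of 27 not called.

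In all reads, 92 of 13178 genes were called after WX-02-23, 56 higher and 36 lower, and 22 of the 24 genes called in T>C reads were called in the same direction. The largest rises were HMOX1 (log2 change 5.26, adjusted p = 2.27e-07), OSGIN1 (2.88, adjusted p = 0.00276) and HSPA1A (2.24, adjusted p = 6.09e-17), with TRIM16L (1.90, adjusted p = 0.0255) and PDK4 (1.79, adjusted p = 2.14e-15) next. HSPA1A, an inducible chaperone gene, rose from 218 ± 34.5 to 1028 ± 84.2 CPM of all reads. The largest falls were ZNF543 (-2.33, adjusted p = 0.0282), NUAK2 (-1.67, adjusted p = 0.0438), CASP9 (-1.37, adjusted p = 0.0310), TRIM24 (-0.99, adjusted p = 0.00363) and KCNJ3 (-0.84, adjusted p = 0.0475). Each of these falls rested on single libraries, and none was called without WX-02-23 replicate 2, where adjusted p was 0.158, 0.118, 0.158, 0.0633 and 0.240 in that order. TRIM16L and KCNJ3 lost the call whichever library was left out. ZNF543 lost it also without DMSO replicate 2 (0.0520) or 3 (0.115) or WX-02-23 replicate 1 (0.138), NUAK2 without DMSO replicate 2 (0.188) or 3 (0.0839) or WX-02-23 replicate 1 (0.296), and CASP9 without DMSO replicate 1 (0.0879) or 2 (0.163) or WX-02-23 replicate 3 (0.198). The count of 92 fell to 61 without WX-02-23 replicate 1, 41 without replicate 2 and 46 without replicate 3, and 27 genes were called in all 6 such fits. FOXA1 changed by -0.11 in all reads (adjusted p = 0.824).

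The comparison of WX-02-43 with DMSO asks the same of the other stereoprobe. Fewer genes were called, and the rises were again stress genes: TXNRD1, OSGIN1, GDF15, SESN2 and the AP-1 gene JUN. ZNF503 fell, as did ID3, an inhibitor of DNA binding, RGS2, a regulator of G protein signalling, and TUBB. FOXA1 and SF3B1 were not called. In T>C reads 10 of 10722 genes were called, 5 higher and 5 lower, of which 4 higher and 0 lower changed at least 2-fold.

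OSGIN1 rose from no T>C read in DMSO to 48.2 ± 12.5 CPM in WX-02-43, at least 25.4-fold higher (adjusted p = 0.000973). TXNRD1 rose to 664 ± 65.9 CPM from 243 ± 44.4, a log2 change of 1.45 (SE 0.23, adjusted p = 0.000558). GDF15 rose to 1883 ± 170.3 CPM from 766 ± 30.5, a log2 change of 1.30 (SE 0.14, adjusted p = 1.73e-07). SESN2 rose to 919 ± 31.3 CPM from 360 ± 116.2 (log2 change 1.35, adjusted p = 0.00197), and the call was lost without DMSO replicate 1 (adjusted p = 0.0511). JUN (chromosome 1, 59246463 to 59247746) rose to 2046 ± 119.7 CPM from 1084 ± 103 (log2 change 0.92, SE 0.13, adjusted p = 4.38e-05). ZNF503 (chromosome 10, 77157588 to 77158506) fell to 3142 ± 51.5 CPM from 5262 ± 409, a log2 change of -0.74 (SE 0.09, adjusted p = 3.74e-06). RGS2 (chromosome 1, 192780727 to 192781407) fell to 4412 ± 189 CPM from 6072 ± 304 (log2 change -0.46, adjusted p = 0.000973). ID3 (chromosome 1, 23884421 to 23885450) fell to 4808 ± 179 CPM from 6367 ± 348 (log2 change -0.41, adjusted p = 0.0233), but was not called without DMSO replicate 2 (0.0563) or 3 (0.181) or without any WX-02-43 replicate (0.278, 0.0784 and 0.169). TUBB fell by 0.73 (adjusted p = 0.0338, 21.5% multimapping), and lost the call without DMSO replicate 2 (0.93) or any WX-02-43 replicate (0.209, 0.166 and 0.111). The other 7 genes were called whichever of the 6 libraries was left out. The log2 change of FOXA1 was -0.15 (95% interval -0.38 to 0.08). SF3B1 stood at 0.17 (-0.93 to 1.26), and its sign turned without DMSO replicate 3 (-0.01) or WX-02-43 replicate 2 (-0.06). Groups did not overlap in 1279 genes (11.9%), against 10% by chance.

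By list, 6 of 17 moved after WX-02-43, 4 up and 2 down, and 5 of them hold with an estimated correlation. Heat shock genes rose by a median of 0.45 over 27 members (camera adjusted p = 7.71e-09, and adjusted p = 0.0163 with an estimated correlation), although 0 of the 27 were called by edgeR over all genes and 4 were higher when adjusted over the list alone. HSPA1B (log2 change 0.84, adjusted p = 0.110), HSPA1A (2.00, adjusted p = 0.302) and HSPH1 (1.00, adjusted p = 0.639) were among the members not called. Over all genes, 409 had an unadjusted p under 0.05 and DESeq2 called 46. NRF2 and electrophile response genes rose by a median of 0.43 over 25 members (camera adjusted p = 7.71e-09, and adjusted p = 0.0188 with an estimated correlation), with TXNRD1 and OSGIN1 called higher, 0 lower and 23 not called, and 4 higher when adjusted over the list alone. HMOX1 of that list was not called (log2 change 2.85, adjusted p = 0.856). Integrated stress and unfolded protein response genes rose by a median of 0.22 over 32 members (camera adjusted p = 0.000145, and adjusted p = 0.0163 with an estimated correlation), with SESN2 higher, 0 lower and 31 not called, and 5 higher when adjusted over the list alone. CHAC1 (1.14, adjusted p = 0.301) and DDIT4 (1.14, adjusted p = 0.110) of that list were not called. Intronless genes rose by a median of 0.21 over 37 members (camera adjusted p = 0.00148, and adjusted p = 0.0285 with an estimated correlation), with JUN higher, 0 lower and 36 not called, and 6 higher and 1 lower when adjusted over the list alone. SR and hnRNP splicing regulators, such as HNRNPK (-0.32) and HNRNPU (-0.44), fell, with a median of -0.25 over 33 members (camera adjusted p = 0.0132, and adjusted p = 0.0360 with an estimated correlation), with 0 called over all genes or over the list alone. Cell cycle genes fell, with a median of -0.29 over 38 members (camera adjusted p = 0.0234, but adjusted p = 0.191 with an estimated correlation), also with 0 called.

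In all reads, 22 of 13178 genes were called after WX-02-43, 13 higher and 9 lower, and 6 of the 10 genes called in T>C reads were among them in the same direction. HMOX1 (log2 change 3.15, adjusted p = 0.00244) and HSPA1A (1.79, adjusted p = 1.98e-13) led the rises, with CYP1B1 (1.11, adjusted p = 0.0215), CHAC1 (1.102, adjusted p = 0.00220) and GDF15 (1.03, adjusted p = 6.27e-11). PPP1R10 (-1.43, adjusted p = 0.00786), ZNF503 (-0.92, adjusted p = 1.36e-09), ID2 (-0.59, adjusted p = 1.39e-06) and IER2 (-0.51, adjusted p = 0.0176, 65.5% multimapping) were among the largest falls. CYP1B1 was not called without DMSO replicate 1 (0.0612) or 2 (0.272) or WX-02-43 replicate 1 (0.112) or 2 (0.21), and PPP1R10 not without DMSO replicate 2 (0.148) or WX-02-43 replicate 1 (0.189). IER2 was not called without DMSO replicate 2 (0.0706) or any WX-02-43 replicate (0.0807, 0.0954 and 0.117). The count of 22 fell to 14 without DMSO replicate 2, 14 without WX-02-43 replicate 1 and 13 without WX-02-43 replicate 2, and 12 genes were called in every such fit.

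WX-02-23 and WX-02-43, given at the same dose for the same time, were then set against each other. PDK4, TXNRD1, ID3 and RGS2 had more newly made RNA after WX-02-23, and PMEPA1 had less. Relative to DMSO, PDK4 and PMEPA1 moved after WX-02-23 alone, ID3 and RGS2 fell after WX-02-43 alone, and TXNRD1 rose after both. Of 10722 genes, 5 were called, 4 higher and 1 lower after WX-02-23, 306 had an unadjusted p under 0.05, and DESeq2 called 25. PDK4 stood at 1937 ± 236 CPM after WX-02-23 and 765 ± 142 after WX-02-43 (log2 difference 1.34, SE 0.18, adjusted p = 3.22e-05), the only one of the 5 called whichever of the 6 libraries was left out. TXNRD1 stood at 1471 ± 101 and 664 ± 65.9 CPM (1.147, adjusted p = 0.0242), PMEPA1 at 631 ± 43.6 and 1209 ± 144 CPM (-0.94, adjusted p = 0.00322), ID3 at 6580.0 ± 288 and 4808 ± 179 CPM (0.45, adjusted p = 0.0117) and RGS2 at 5793 ± 77.4 and 4412 ± 189 CPM (0.39, adjusted p = 0.0242).

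The count of 5 fell to 3 without WX-02-23 replicate 1, 2 without replicate 2 and 1 without replicate 3, and to 1, 2 and 3 without WX-02-43 replicates 1, 2 and 3. TXNRD1 and RGS2 lost the call in each of the 6 cases, with adjusted p up to 0.241 and 0.439. ID3 lost it without WX-02-23 replicate 2 (0.094) or 3 (0.134) or any WX-02-43 replicate (0.222, 0.0539 and 0.0933), and PMEPA1 without WX-02-23 replicate 3 (0.0525) or WX-02-43 replicate 1 (0.153).

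Of the 27 genes called against DMSO for either stereoprobe, 5 were called between them and 22 were not shown to differ, which does not show that they responded alike. In 15 of those the 95% interval of the difference lay within a log2 change of 1 either way, as for GDF15 (0.29, interval 0.01 to 0.57), JUN (-0.41, interval -0.67 to -0.15) and TFAP2A (-0.65, interval -0.96 to -0.35, adjusted p = 0.159). In the other 7 it was wider, as for HMOX1 (2.04, interval 0.17 to 3.91) and SRXN1 (1.03, interval 0.47 to 1.58, adjusted p = 0.558). The intervals of these examples leave out 0, but they are not adjusted for the number of genes tested. FOXA1 differed by -0.06 (interval -0.29 to 0.17), a sign that turned when T>C reads were scaled by all reads (0.02) or without WX-02-23 replicate 2 (0.03). SF3B1 differed by -0.44 (interval -1.54 to 0.66). Over all 10722 genes the interval lay within that bound in 1161 (10.8%), and in 73.4% of the 1431 genes with a mean of at least 200 T>C reads. Groups did not overlap in 1147 genes (10.7%), against 10% by chance.

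**Figure D2:**
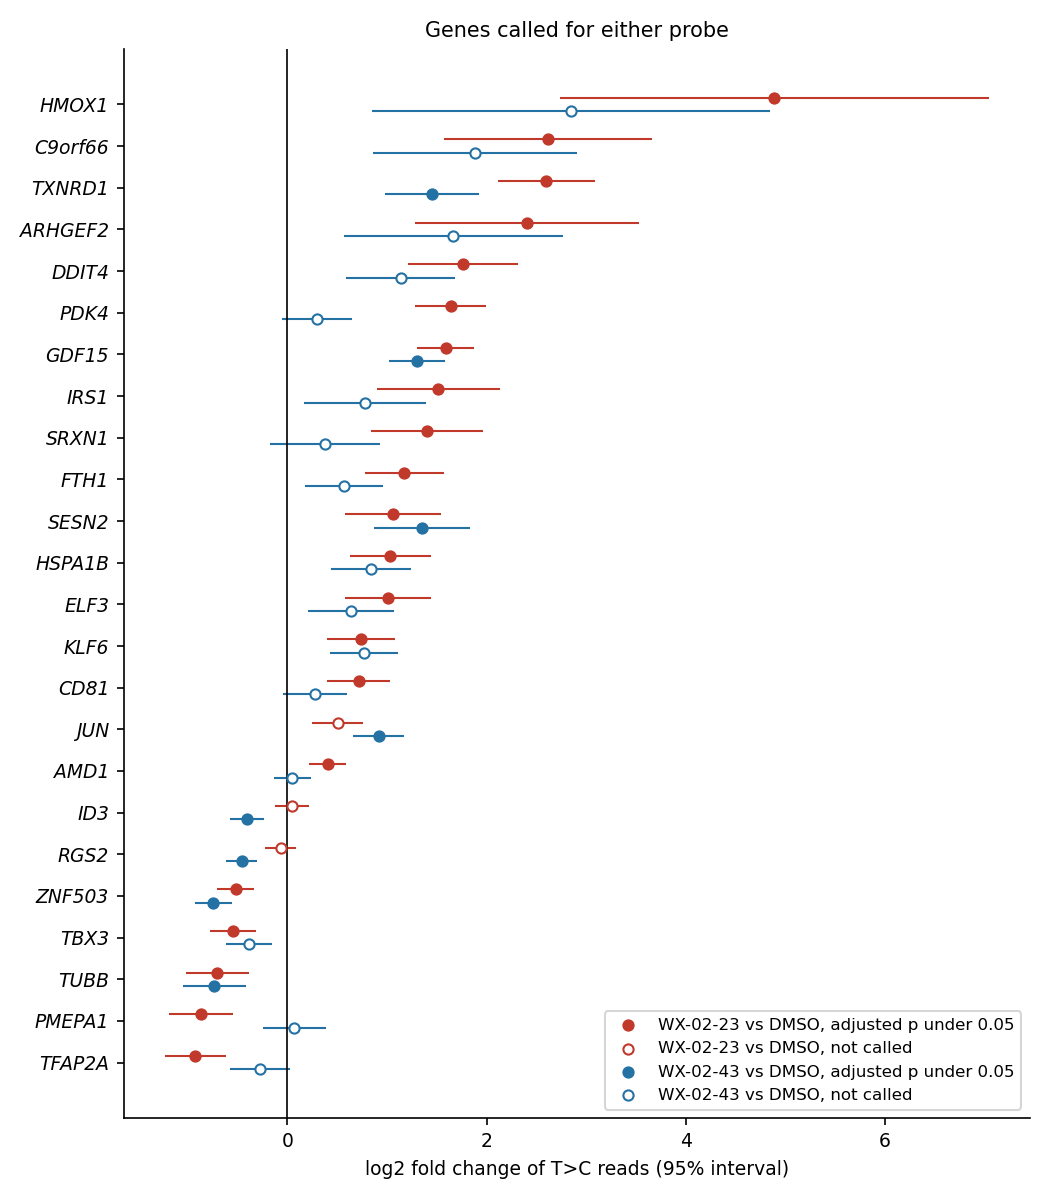
Log2 change in T>C reads against DMSO, with 95% intervals, for 24 of the 27 genes called for either stereoprobe (OSGIN1, at 0 in DMSO, is among those not drawn); red is WX-02-23, blue is WX-02-43, and filled points have an adjusted p under 0.05. PDK4 lies at 1.64 in red, PMEPA1 at -0.87 in red, and TXNRD1 at 2.60 in red and 1.45 in blue. Both stereoprobes are set against the same DMSO libraries, so overlap of a red and a blue interval does not test their difference.

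Among lists, NRF2 and electrophile response genes lay higher after WX-02-23 than after WX-02-43 by a median of 0.38 (camera adjusted p = 0.000301), but not with the other correlation (adjusted p = 0.340 with an estimated correlation). TXNRD1 was their only called member, 24 of 25 were not called, and 3 were higher when adjusted over the list alone. The other 16 lists were not called; ID3 was the called member of the short-lived regulators. In all reads, 20 genes differed, 16 higher and 4 lower after WX-02-23, and the 5 genes above were among them in the same direction. PDK4 (log2 difference 1.48, adjusted p = 3.96e-12), F3 (1.11, adjusted p = 0.0344), ERRFI1 (1.07, adjusted p = 0.0216), IRS1 (0.75, adjusted p = 0.0231) and TXNRD1 (0.69, adjusted p = 0.000919) led the higher genes. ZNF543 (-2.57, adjusted p = 0.0317), RBM47 (-0.74, adjusted p = 0.00312), TFAP2A (-0.56, adjusted p = 0.0256) and PMEPA1 (-0.55, adjusted p = 0.000214) were the lower ones. Leaving out WX-02-23 replicates 1, 2 and 3 gave 11, 8 and 8 genes, leaving out WX-02-43 replicates 1, 2 and 3 gave 8, 11 and 7, and 6 genes were called every time, PDK4, TXNRD1, PMEPA1 and ID3 among them. Without WX-02-43 replicate 3, F3 (0.255), ERRFI1 (0.152), IRS1 (0.152), ZNF543 (0.0779) and TFAP2A (0.184) were not called, and RBM47 was not called without WX-02-23 replicate 3 (0.0605) or WX-02-43 replicate 1 (0.0762).

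The comparison of PladB with DMSO asks for the response to an SF3b inhibitor in the same cells. PladB changed newly made RNA broadly. Relative to the typical gene, intronless genes, JUN among them, EGR1 and the splicing factor genes SRSF2 and HNRNPDL rose. CCND1 (cyclin D1), TFAP2A and many genes with no T>C read left, such as PTCH1 and SCAF4, fell. In T>C reads 1140 of 10722 genes were called, 506 higher (44.4%) and 634 lower, of which 379 and 608 changed at least 2-fold. Scaling by all reads, which keeps the lower share of T>C reads in the comparison, whether from less new RNA or from lower labelling, moved the median gene from -0.36 to -1.154 and gave 1834 calls, 85 higher (4.63%) and 1749 lower, with 720 genes called under both. A fit of only the 6 libraries gave 493 calls, 323 higher and 170 lower, so that the balance of directions turned, and DESeq2 gave 1922, 673 higher and 1249 lower. Changes below are relative to the T>C reads themselves unless said otherwise.

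CCND1 (chromosome 11, 69466051 to 69469242) fell from 9871 ± 1241 to 3016 CPM, a log2 change of -1.71 (SE 0.09, adjusted p = 6.18e-18). TFAP2A (chromosome 6, 10396916 to 10398649) fell from 2223 ± 306 to 282 ± 36.0 CPM (log2 change -2.98, SE 0.16, adjusted p = 2.44e-17). SRRM4, a neural splicing factor gene, went from 343 ± 10.0 to 1.12 ± 1.02 CPM, with 1633 T>C reads in DMSO and 3 in PladB (adjusted p = 2.84e-15). PTCH1 (chromosome 9, 98205264 to 98209193) had 134 ± 38.7 CPM in DMSO and no T>C read in PladB, at least 36.0-fold lower (adjusted p = 1.49e-07). SCAF4 (at least 25.6-fold lower), EFNA4 (18.3), MKL2 (17.8), RNF24 (17.4), RFX3 (15.7), FBXL5 (14.6) and EIF4ENIF1 (14.4) also had no T>C read in PladB, with adjusted p from 7.13e-07 to 0.000761. SCAF4 had 869 reads of both kinds in DMSO and 695 in PladB (log2 change -0.17 in all reads, adjusted p = 0.752), whereas PTCH1 fell in all reads too (-2.33, adjusted p = 8.62e-07). All of the T>C calls above held whichever of the 6 libraries was left out, as they did for 569 of the 1140 genes, and 1119 genes were called without PladB replicate 2, the library with the fewest genes detected.

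Among rises, JUN went from 1084 ± 103 to 3796 ± 611 CPM (log2 change 1.81, SE 0.13, adjusted p = 1.36e-13) and EGR1 from 484 ± 82.7 to 2278 ± 295 CPM (2.23, SE 0.17, adjusted p = 1.16e-12). Scaled by all reads they still rose, by 1.01 and 1.43. SRSF2 (chromosome 17, 74730197 to 74732242) rose from 317 ± 29.1 to 1208 ± 173 CPM (log2 change 1.93, SE 0.21, adjusted p = 7.60e-09). HNRNPDL rose from 238 ± 64.5 to 963 ± 117 CPM (2.02, adjusted p = 3.86e-07), and RBM48 (chromosome 7, 92166252 to 92169795) from 37.7 ± 3.01 to 275 ± 49.2 CPM (2.86, SE 0.45, adjusted p = 1.46e-05). The 7 genes that the naming rule places above RBM48 were near the floor, with 0 T>C reads in DMSO for FAM160A2 (at least 21.4-fold higher), SLC17A7 (16.01) and SULT1A3 (15.4). CLEC11A, ARFRP1, S100A6 and NDUFAF1 had 1, 2, 3 and 12 T>C reads in DMSO against 88, 106, 60 and 216 in PladB. T>C reads of SLC17A7, SULT1A3 and ARFRP1 carried 1 T>C change each in PladB, the level that single errors or variants give, so their rises are uncertain. Each of the 7 lost the call without a single library. FAM160A2, SLC17A7, SULT1A3, CLEC11A and S100A6 lost it without any DMSO replicate, the first 3 with adjusted p from 0.0717 to 0.0856, CLEC11A with 0.0609 to 0.118 and S100A6 with 0.0591 to 0.105. FAM160A2 (0.183), SLC17A7 (0.0677) and CLEC11A (0.137) lost it also without PladB replicate 3, and SULT1A3 (0.0729), ARFRP1 (0.0854) and NDUFAF1 (0.0757) without PladB replicate 2. NDUFAF1 lost it further without DMSO replicate 2 (0.128) or 3 (0.1) or by DESeq2 (0.0996). Scaled by all reads, FAM160A2 (0.0504), CLEC11A (0.0727) and NDUFAF1 (0.0909) were not called either.

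FOXA1 (chromosome 14, 38058757 to 38060569) rose from 2656 ± 300.1 to 3723 ± 231 CPM relative to other newly made RNA (log2 change 0.49, SE 0.11, adjusted p = 0.00309), but scaled by all reads it changed by -0.31 (adjusted p = 0.0594). In all reads FOXA1 rose from 516 ± 24.8 to 826 ± 68.6 CPM (0.68, adjusted p = 2.76e-07). SF3B1 was not called (0.56, interval -0.54 to 1.66, adjusted p = 0.591), and its sign turned when scaled by all reads (-0.23).

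**Figure D3:**
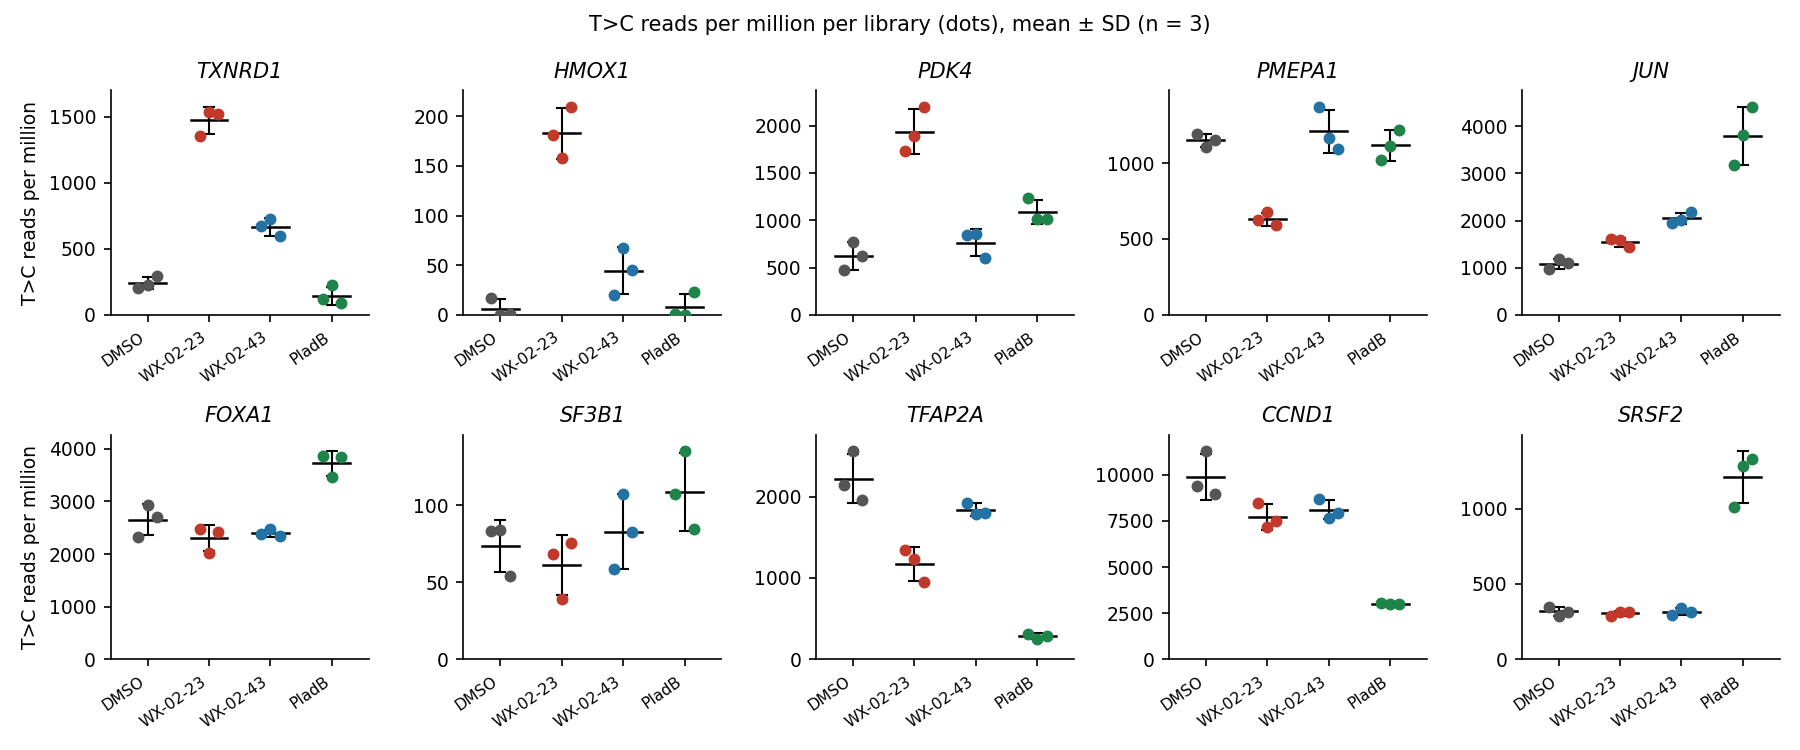
T>C reads of 10 genes in CPM scaled to T>C reads (linear axes from 0) in DMSO, WX-02-23, WX-02-43 and PladB, with dots for libraries and bars for the mean ± SD of 3. TXNRD1 and PDK4 are highest in WX-02-23 (1471 and 1937), and in PladB CCND1 and TFAP2A are lowest while SRSF2 and JUN are highest; FOXA1 is higher in PladB on this scale but lower (-0.31) when scaled by all reads.

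By list, 4 of 17 rose relative to other newly made RNA after PladB, and 3 of them hold with an estimated correlation. Intronless genes rose by a median of 0.92 over 37 members (camera adjusted p = 5.60e-13, and adjusted p = 0.000839 with an estimated correlation), with 16 higher, 1 lower and 20 not called, and 19 higher and 1 lower when adjusted over the list alone. JUN, HNRNPA0 (log2 change 1.32, adjusted p = 1.099e-08), EID1 (1.31, adjusted p = 4.90e-06) and IER2 (1.12, 65.5% multimapping) were its examples, and the median was 0.13 when scaled by all reads. SR and hnRNP splicing regulators rose by a median of 0.61 over 33 members (camera adjusted p = 1.97e-06, and adjusted p = 0.00293 with an estimated correlation), but the median was -0.19 when scaled by all reads. In that list 10 were higher, 2 lower and 21 not called, alike when adjusted over the list alone, and SRSF7 (1.54, adjusted p = 6.84e-05) and HNRNPA1 (1.55, adjusted p = 4.80e-06, 20.6% multimapping) joined SRSF2 and HNRNPDL. SF3b and U2 factors rose by a median of 0.46 over 22 members (camera adjusted p = 0.000143, and adjusted p = 0.00985 with an estimated correlation), again with a median below 0 when scaled by all reads (-0.33). U2AF2 (log2 change 1.39, adjusted p = 1.87e-06), SF3B5 (1.35, adjusted p = 0.000134), SF3B6 (1.74, adjusted p = 0.00177) and PHF5A (1.47, adjusted p = 0.0297) were higher, 0 lower and 18 not called, with 6 higher when adjusted over the list alone. T>C reads of U2AF2 carried 1.03 T>C changes each in PladB (1.27 in DMSO) and those of HNRNPA1 1.153 (1.45 in DMSO), near that level of 1, so both rises are uncertain. PHF5A lost the call without DMSO replicate 1 (0.134) or 2 (0.0871) or PladB replicate 1 (0.0899) or 3 (0.0832). Immediate early genes had a median of 0.14 (-0.72 when scaled by all reads) but a mean of -0.30 over 35 members, and camera called them higher (adjusted p = 0.00596, but adjusted p = 0.266 with an estimated correlation and 0.402 when scaled by all reads). Of them 9 were higher, EGR1, JUN and MYC (1.083, adjusted p = 1.02e-06) included, 4 lower and 22 not called, with 12 higher and 5 lower when adjusted over the list alone. Scaled by all reads, 3 intronless genes were higher and 3 lower, 3 and 4 of the SR and hnRNP regulators, 1 and 1 of the SF3b and U2 factors and 2 and 8 of the immediate early genes. On that scale EID1 (adjusted p = 0.0679), IER2 (0.0826), SRSF7 (0.0577), SF3B5 (0.109), SF3B6 (0.0929), PHF5A (0.323) and MYC (0.191) were no longer called.

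Lists not called after PladB held from 0 to 14 called genes, in some lists in both directions, but with T>C reads scaled by all reads 0 of their members were called higher. Prostate luminal lineage factors had FOXA1 and SOX4 (log2 change 0.92, but 0.13 and adjusted p = 0.618 scaled by all reads) higher and 7 lower, with GRHL2 (-3.37, adjusted p = 0.000198), ONECUT2 (-2.14, adjusted p = 1.50e-05) and TFAP2A among them (camera adjusted p = 0.105). FKBP5 (-2.43, adjusted p = 3.33e-05), CAMKK2 (-5.24, adjusted p = 0.000368), C1orf116 (-0.90, adjusted p = 0.00619) and NDRG1 (-3.31, adjusted p = 0.0267) fell. C1orf116 lost its call without DMSO replicate 2 (0.0925) and NDRG1 without DMSO replicate 3 (0.0708) or PladB replicate 3 (0.0764). Short-lived regulators had HEXIM1, named after its value was seen, higher (adjusted p = 0.0414, but 0.215 and 0.114 without DMSO replicates 1 and 2, and 0.0606 and 0.146 without PladB replicates 1 and 3) and 7 lower, with ID2 (-0.70), ID3 (-0.72), ID4 (-1.084) and HES1 (-1.44) as examples (camera adjusted p = 0.133). ID2 T>C reads fell from 57668 to 18562 summed over libraries while its reads of both kinds went from 98638 to 100520. Integrated stress and unfolded protein response genes had 5 higher and 9 lower, HSPA5 rising (0.85, but 0.05 and adjusted p = 0.805 scaled by all reads) and CHAC1 (-3.26), SESN2 (-2.09) and PSAT1 (-2.28) falling (camera adjusted p = 0.677). NRF2 genes had TXN higher (adjusted p = 0.358 scaled by all reads, and 0.0589 without DMSO replicate 2; 0.995 T>C changes per T>C read in PladB) and GCLC (-4.26), GCLM (-2.38), SLC7A11 (-2.84) and TXNRD1 lower (camera adjusted p = 0.677). Heat shock genes had 5 higher and 1 lower (camera adjusted p = 0.175), cell cycle genes 0 and 4 (0.352), p53 targets 1 and 4 (0.501), apoptosis regulators 2 and 4 (0.166), cholesterol synthesis genes 2 and 0 (0.128), MYC and ribosome biogenesis genes 2 and 1 (0.384), neuroendocrine markers 0 and 1 (0.128), and stromal markers 0 and 0 (0.105).

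Scaled by all reads, 6 of these lists were called lower and 1 higher by camera. Luminal lineage factors had 16 of 27 lower (adjusted p = 7.80e-06, and adjusted p = 0.00575 with an estimated correlation), short-lived regulators 16 of 28 (0.000155, and adjusted p = 0.0459 with an estimated correlation) and integrated stress genes 16 of 32 (0.000157, and adjusted p = 0.0204 with an estimated correlation). Cell cycle genes had 11 lower (adjusted p = 0.0209, but adjusted p = 0.135 with an estimated correlation), p53 targets 9 (0.0432, but adjusted p = 0.0960 with an estimated correlation) and apoptosis regulators 5 (0.0432, but adjusted p = 0.135 with an estimated correlation). Stromal markers were the list called higher (adjusted p = 0.0137, but adjusted p = 0.123 with an estimated correlation), with 0 of 7 called and a median of -0.52. Not called on this scale were NRF2 genes with 10 lower (adjusted p = 0.0977), MYC and ribosome biogenesis genes with 8 (0.423), heat shock genes with 6 (0.525), cholesterol synthesis genes with 2 (0.387) and neuroendocrine markers with 2 (0.144).

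In all reads 3971 of 13178 genes were called after PladB, 1828 higher and 2143 lower, of which 194 and 1268 changed at least 2-fold. Of the 1140 genes called in T>C reads, 851 were called in the same direction in all reads and 12 in the opposite one. The largest falls were DAGLA (at least 34.2-fold), ZNF225 (20.2), ELAC1 (20.0), CCDC102A (19.7) and CLCN6 (19.5), each with no read in PladB. The largest rises, RASAL3, C1R, ZG16, DKKL1 and ACTL8, came from means under 7.25 CPM of all reads in PladB and lost the call without PladB replicate 2, with adjusted p of 0.0841, 0.114, 0.172, 0.0737 and 0.094. They lost it without DMSO replicates too, RASAL3 (0.058 and 0.0529) and ACTL8 (0.0637 and 0.06) without 1 and 3, and C1R, ZG16 and DKKL1 without any of the 3, with adjusted p up to 0.0908, 0.11 and 0.108; DKKL1 also lost it without PladB replicate 1 (0.0744). Groups did not overlap in 2989 genes (27.9%) in T>C reads, against 10% by chance.

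The overlap of calls asks how far the stereoprobe changes resembled those of an SF3b inhibitor. Of the 24 genes called after WX-02-23, 6 changed in the same direction after PladB and 6 in the opposite one. CD81, HSPA1B, KLF6 and PDK4 rose in both, TBX3 and TFAP2A fell in both, and TXNRD1, SESN2, ELF3, ARHGEF2 and TUBB were among those that went opposite ways. Single libraries carried part of this: the WX-02-23 calls of CD81, HSPA1B, KLF6 and TBX3 were lost without some libraries, as given above, and the PladB call of HSPA1B without any DMSO replicate (0.105, 0.09 and 0.0685) or PladB replicate 1 (0.244). Scaled by all reads, none of the 4 shared rises remained. CD81 was not called after WX-02-23 (adjusted p = 0.0514). After PladB, HSPA1B (-0.17) and KLF6 (-0.16) turned direction and PDK4 stood at 0.02 (adjusted p = 0.958). TUBB turned direction after PladB too (-0.29, not called), so it no longer went opposite to either stereoprobe. On that scale 0 genes were higher in both, 5 were lower in both (PMEPA1, TBX3, TFAP2A and ZNF503 among them) and 9 went opposite ways. That scale keeps the lower T>C share of PladB, with 1749 of 1834 PladB calls lower and the median gene at -1.154. Shared falls and opposite calls there thus include that general fall. In all reads PMEPA1 was called lower after WX-02-23 and higher after PladB, and HSPA1B the reverse. For the calls scaled to T>C reads, independent lists of their sizes would share 0.85 higher and 0.355 lower genes. No such level was computed for opposite calls or for calls scaled by all reads. With 6 genes in the same direction and 6 in the opposite one, the calls of WX-02-23 and PladB show no common direction. Independence also leaves out that genes with many T>C reads are more readily called in any comparison. The overlap of 6 became 3 without DMSO replicate 2, 10 without DMSO replicate 3 and 2 without WX-02-23 replicate 2. WX-02-43 shared JUN and ID3 with PladB and had 4 opposite (RGS2, SESN2, TUBB and TXNRD1), where independent lists would share 0.236 higher and 0.296 lower. The stereoprobes shared 7 calls with each other, GDF15, OSGIN1, SESN2, TXNRD1, TUBB and ZNF503 among them, with 0 opposite, where independent lists would share 0.00839 and 0.0028. In 20 simulations of unchanged groups, with the DMSO libraries drawn too, a comparison had at most 1 call, so their shared count of 0 was bound to come out and gives no chance level.

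Across 8271 genes, which are not independent replicates, log2 changes had a correlation of 0.228 for WX-02-23 and PladB, 0.207 for WX-02-43 and PladB and 0.563 for the stereoprobes. In the simulations, where the shared DMSO libraries alone link the changes, it was 0.499, 0.492 and 0.503. Covariances were 0.326, 0.284 and 0.333, against simulated ones of 0.456, 0.450 and 0.455, so that the differences were -0.130, -0.166 and -0.122. Simulated changes varied more than the real ones of the stereoprobes (variance 0.904 against 0.619 for WX-02-23 and 0.566 for WX-02-43), so these differences give no estimate of a shared effect. The 3 DMSO libraries cannot be split into parts of 2, so the part of each overlap and correlation that comes from the shared controls was not measured.

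Among the remaining lists, p53 targets had GDF15 and SESN2 higher, 0 lower and 26 of 28 not called after either stereoprobe (camera adjusted p = 0.647 for WX-02-23 and 0.0684 for WX-02-43). In all reads camera called p53 targets higher after WX-02-23 (adjusted p = 0.00453, but adjusted p = 0.0773 with an estimated correlation) and after WX-02-43 (adjusted p = 0.000136, and adjusted p = 0.0297 with an estimated correlation). After WX-02-23, camera adjusted p was 0.647 for MYC and ribosome biogenesis genes, 0.355 for SF3b and U2 factors, 0.0717 for SR and hnRNP regulators, 0.0709 for cholesterol synthesis genes, 0.800 for apoptosis regulators, 0.647 for short-lived regulators, 0.647 for neuroendocrine markers and 0.245 for stromal markers. After WX-02-43, luminal lineage factors (0.466) had 0 higher and 1 lower, short-lived regulators (0.367) had ID3 lower, and immediate early genes (0.208) had JUN higher. After WX-02-43 no member was called among MYC and ribosome biogenesis genes (camera adjusted p = 0.645), SF3b and U2 factors (0.879), apoptosis regulators (0.521), cholesterol synthesis genes (0.427), neuroendocrine markers (0.645) and stromal markers (0.427). Median, mean and test differed in sign after WX-02-23 for apoptosis regulators (median 0.10, mean -0.08, test down), short-lived regulators (both 0.01, test down) and neuroendocrine markers (-0.09, 0.04, test down). They differed after WX-02-43 for luminal lineage factors (-0.15, 0.00478, test down), immediate early genes (0.01, -0.14, test up), MYC and ribosome biogenesis genes (both 0.01, test down), neuroendocrine markers (-0.08, 0.81, test up) and stromal markers (-0.34, 0.23, test up). After PladB they differed for heat shock genes (0.01, -0.35, test up), cholesterol synthesis genes (0.30, -0.13, test up) and MYC and ribosome biogenesis genes (-0.06, -0.30, test up). The basal and immune marker lists had under 5 members tested in T>C reads, and in all reads their 8 and 5 tested members had 0 calls by edgeR in each comparison. Mitochondrially encoded genes had no interval that passed the filter and were not tested.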

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

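The tests of explanations in this part were set before their results were seen. The design named the permutation test for the share of T>C reads, not for T>C changes per read. Each result stood out as a signal in data that the comparisons of the report do not use, namely T>C changes per read of the stereoprobes, spike-in reads and noncoding intervals, beyond its level in the DMSO libraries.

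T>C reads from WX-02-43 libraries carried more T>C changes per read, 2.408 ± 0.0039 (SD, n = 3), than those from DMSO libraries (1.814 ± 0.035), and WX-02-23 libraries lay between them (1.986 ± 0.0099). All 3 libraries of each stereoprobe lay above all 3 of DMSO, with an exact permutation p of 0.1, the smallest that 3 against 3 can give. Lying above every DMSO library was the condition for being flagged here. That p was therefore fixed by the choice and adds no support. Fewer T>C reads that do not come from labelling would lower the share of T>C reads and change heavily labelled genes little, but in 341 genes with at least 50% T>C reads in DMSO the WX-02-43 ratio to DMSO was 1.387 (spread 0.0078), at a T>C share of 64.9% against 63.9%. A different mix of genes would leave the ratio within a gene near 1, but its median for WX-02-43 was 1.342 (quartiles 1.144 to 1.559). These values argue against both explanations; a higher rate of 4-thiouridine uptake or conversion, or a difference in handling between the groups, was not tested, and may be a candidate explanation.

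Spike-in intervals held 12 reads in WX-02-23 replicate 2, 8 in WX-02-43 replicate 2 and 0 in the other 10 libraries. The noncoding ANKRD30BL interval (chromosome 2, 132905164 to 133015542 in hg19) held 21.53% ± 3.37 of T>C reads over all intervals in PladB, against 13.9% ± 0.994 in DMSO. Its own T>C reads numbered 342910 ± 28871 in PladB and 322100 ± 6584.1 in DMSO, so that the larger share came mostly from fewer T>C reads elsewhere (a mean of 948450 on coding genes, against 1522300). Of all reads in this interval, 81.8% ± 0.573 had T>C in PladB and 83.2% ± 0.608 in DMSO. On coding genes that share fell from 9.45% in DMSO to 5.44% in PladB. T>C reads of this interval may therefore not measure newly made RNA, and their source was not tested. Of 1928 noncoding intervals, all on the minus strand, tested with edgeR, 5 were called after WX-02-23 (4 higher, 1 lower), 4 after WX-02-43 (2 higher, 2 lower) and 132 after PladB (96 higher, 36 lower). These counts were scaled to T>C reads on coding genes, which were fewer after PladB. On that scale ANKRD30BL was called higher after PladB (log2 change 1.06, adjusted p = 7.23e-14). Noncoding intervals were not tested scaled by all reads, so the PladB rises hold only relative to coding T>C reads. LOC102724738 (chromosome 7, 62807178 to 62810444) rose in all 3, by a log2 change of 4.64 (adjusted p = 1.66e-06), 4.05 (adjusted p = 3.62e-05) and 5.79 (adjusted p = 1.25e-09). Its WX-02-43 libraries varied widely, at 99.7 ± 83.1 CPM against 5.84 ± 3.89 in DMSO. SNAR-E rose by 0.90, 0.66 and 1.48 in the same order. A lower interval after WX-02-43, named ZNF503, shares reads with the coding gene of that name.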

How the results depend on the processing

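The joined coding intervals of the main tests were chosen after the files were seen, whereas the design had named the sum over every interval of a gene. Also chosen only after the data were seen were the tests with counts divided by the ratio of variance to mean and without genes under 1.2 T>C changes per T>C read. The tests without PladB replicate 2 throughout were chosen then too. Of results for named genes, 2823 had the same direction and side of the threshold, 294 lost the call, 44 gained one and 12 turned direction; of counts and shares, 132 were alike, 52 moved and 3 turned. The cause was not tested except where said. In the simulated data, depth and spread between replicates limited the T>C calls. Few genes there had enough T>C reads for a 2-fold change to be called. Simulated changes varied more than the real ones of the stereoprobes, so this limit may be overstated.

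DESeq2 called 64 genes in T>C reads after WX-02-23, 46 after WX-02-43, 1922 after PladB and 25 between the stereoprobes, and in all reads 161, 40 and, between the stereoprobes, 38. With no filter on low counts, T>C calls were 16 after WX-02-43 and 8 between the stereoprobes, and all-read calls 140 after WX-02-23, 36 after WX-02-43 and 33 between the stereoprobes. With only the 6 libraries compared, PladB had 493 T>C calls, with 323 higher and 170 lower where the report has 506 and 634, and WX-02-23 had 56 in all reads, from fewer libraries. Adding up every interval, the unit named in the design, gave 12 T>C calls after WX-02-23, where the report has 24. It gave 1 T>C call between the stereoprobes (5 in the report) and 59 calls in all reads after WX-02-23 (92 in the report). Testing each interval by itself gave 2 between the stereoprobes. Counts divided by the ratio of variance to mean gave 65, 36, 699 and 13 T>C calls in the 4 comparisons and 167 in all reads after WX-02-23.

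Scaling T>C reads by all reads gave 1834 PladB calls and 10 PladB lists, and turned the PladB change of FOXA1 (-0.3071), HSPD1 (-0.06025), MCL1 (-0.06742), SF3B1 (-0.2289) and UBB (-0.05404) and the difference of FOXA1 between the stereoprobes (0.01726); that scaling keeps the lower T>C share of PladB in the comparison. With fry 11 PladB lists were called, and between the stereoprobes 0 lists with fry or with an estimated correlation, against 1 with camera. By percent of T positions converted, the WX-02-43 difference from DMSO was 0.2071 and that of WX-02-23 from WX-02-43 was -0.1021.

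Leaving out each library in turn gave 12 (without WX-02-23 replicate 2) to 23 T>C calls after WX-02-23, 8 to 14 after WX-02-43, 840 to 1154 after PladB and 1 to 3 between the stereoprobes. In all reads it gave 41 to 86, 13 to 29, 3269 to 3652 and 7 to 11. The overlap of WX-02-23 and PladB ran from 2 to 10. The difference in labelled share from DMSO ran from -0.03793 to 0.3854 for WX-02-23, -0.5794 to -0.156 for WX-02-43 and -4.24 to -3.817 for PladB. SF3B1 after WX-02-43 ran from -0.06249 to 0.367 in T>C reads, and between the stereoprobes FOXA1 ran from -0.1134 to 0.03066 in T>C reads and SF3B1 from -0.04586 to 0.1133 in all reads, around a reported 0.01.

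Libraries with the same replicate number did not deviate together (correlations -0.025 to 0.026 in T>C reads). A replicate block gave 25, 14, 1089 and 5 T>C calls, 104, 24, 3953 and 20 in all reads, an overlap of 7, and 6, 6, 5 and 1 lists, stromal markers (adjusted p = 0.0485) being the list added after PladB.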

Other observations

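Among the tests of explanations here, the comparison of the change in T>C reads with that in all reads was chosen only after the result was seen. The other tests of explanations were set before. In all reads, heat shock genes rose after both stereoprobes, with more called members than in T>C reads. After WX-02-23, 7 of 28 were called higher and 0 lower (14 higher when adjusted over the list alone; camera adjusted p = 2.84e-27, and adjusted p = 0.000559 with an estimated correlation), and after WX-02-43, 3 and 0 (13 higher when adjusted over the list alone; camera adjusted p = 1.70e-28). Short-lived zinc finger and transcription regulators fell after WX-02-43, with ID1, ID2 and ID3 lower (camera adjusted p = 1.05e-05, and adjusted p = 0.0126 with an estimated correlation). SR and hnRNP splicing regulators fell as a list after WX-02-23 (camera adjusted p = 4.92e-05) and WX-02-43 (9.11e-07), each with 0 of 33 called by edgeR (over all genes, 1147 and 772 had an unadjusted p under 0.05 and DESeq2 called 161 and 40), but rose after PladB (1.65e-05), where 17 were higher and 3 lower. Other lists called in all reads but not in T>C reads were p53 targets, higher after WX-02-23 (camera adjusted p = 0.00453, but adjusted p = 0.0773 with an estimated correlation) and WX-02-43 (0.000136, and adjusted p = 0.0297 with an estimated correlation), luminal lineage factors, lower after WX-02-23 (camera adjusted p = 0.0390, but adjusted p = 0.0690 with an estimated correlation), and cell cycle genes, lower after PladB (0.0394, but adjusted p = 0.170 with an estimated correlation). Between the stereoprobes, 5 lists were called in all reads, 0 of them with an estimated correlation.

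The PladB change in T>C reads went with the number of exons of a gene. The 207 genes whose reference transcripts have 1 exon had a median log2 change of 0.77 (-0.02 scaled by all reads), with 50 higher and 1 lower. The 4507 genes with over 10 exons had a median of -0.71, with 80 higher and 339 lower. The median of 1-exon genes lay 1.161 above that of genes with 2 or more exons. The Spearman correlation of exon number with the change was -0.198 across 10500 genes, which are not independent replicates. Both values met the bounds set beforehand for an effect of exon number. With gene length and T>C level ranked out, the correlation with exon number was -0.04965. That lay only just within the range set beforehand for an effect of gene length without one of exon number. The correlation of gene length with the change was -0.247, and with exon number and T>C level ranked out it was still -0.156. Both explanations thus met their bounds, so these tests do not decide between gene length and exon number. The difference of 1-exon genes was not tested with gene length ranked out.

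T>C reads from PladB libraries carried 1.383 ± 0.0309 T>C changes (SD, n = 3), fewer than the 1.814 ± 0.035 of DMSO. Dilution by reads that do not come from labelling would change little in the 341 genes with at least 50% T>C reads in DMSO, but there the PladB ratio was 0.7672 (spread 0.0075), at a T>C share of 34.6% against 63.9%. That argues against dilution as the whole explanation. Lower labelling of each new transcript, from less uptake, a later start or a shift in what was made, was not tested and may remain open. The exact permutation p of this difference was 0.1, from a test that the design named only for the share of T>C reads.

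Genes higher in T>C reads after PladB included 153 of 506 (30.2%) with under 1.2 T>C changes per T>C read in DMSO, a level at which reads from sequencing errors or variants are a candidate source. Scaled by all reads, the median change was 0.5861 in these and 0.4195 in the 348 genes with at least 1.2. By the bounds set beforehand, 0.5861 counted against that source and 0.4195 decided nothing. Those bounds took all reads as unchanged, but all reads rose by a median of 0.569 and 0.594. A further test was therefore added after this result was seen. In the 153 genes the change in T>C reads minus that in all reads had a median of 0.01647 (quartiles -0.175 to 0.278), as where T>C reads merely follow all reads. Their T>C reads in PladB carried a median of 1.011 T>C changes. For these genes the later test goes with that source and the earlier one against it, so the source was not settled. In the 348 genes the same difference was -0.1958 (quartiles -0.423 to 0.0570), within the same bound of 0.25, but T>C reads in PladB carried a median of 1.469 T>C changes, above the 1.2 set for that source. The first value goes with that source and the second with labelling, so the 2 cannot be told apart in the 348 genes.

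Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05. In T>C reads the real split called 24, 10, 1140 and 5 genes for WX-02-23, WX-02-43, PladB and the stereoprobes against each other, in all reads 92, 22, 3971 and 20. The highest of the other splits called 0 in each of the 8 comparisons, so that 1 of 10 splits called as many genes as the real one. The other splits mix libraries of the groups compared, so a real change becomes spread within groups and lowers their calls. Their count of 0 therefore gives no chance level.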
